A study of Mus musculus with 8 samples.

How the data were processed

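Gene expression was measured on Affymetrix mouse arrays in sorted hematopoietic stem cells cultured with eltrombopag or its vehicle, 4 arrays per group. Per the labels' protocols, RNA from the lysed cells was amplified and biotin-labelled with a kit that primes at the 3' end, starting from about 10 ng. The deposited values are log2 expression values, 1 per probe set and array, and the submitters' processing notes name RMA, oligo and limma without versions. RMA subtracts background, sets the arrays to a common distribution and summarises the probes of a probe set, so absolute differences in RNA content between arrays are removed before deposit. The genome build behind the probe sets is not given in the sources used here, and no coordinates are reported.

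The table held 22206 probe sets on 8 arrays. The platform annotation paired 19572 of them with 1 gene symbol, 0 with several, and left 2634 unnamed here. All named probe sets gave 19505 genes, and for the 55 genes with several probe sets the probe set with the highest mean over all arrays stood for the gene. No filter was set on dim genes. In every pair of arrays, 0 probe sets had equal values, compared unrounded with a tolerance of 0. Signal over background per probe set is not part of the values used here. The number of arrays limits the precision. The median half-width of a gene's 95% interval for the log2 difference was 0.28.

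Groups and replicate numbers came from the sample titles. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings), two-sided, on the log2 values as deposited, with group as the only term. Benjamini-Hochberg adjustment ran over all genes, and a gene was called at adjusted p under 0.05. Where p-values of limma are printed without adjustment, this is said. Array-level values were compared with an exact permutation test, two-sided, whose smallest possible p for 4 against 4 arrays is 0.0286.

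Before the data were examined, 36 gene lists were fixed from general knowledge of the cells and the drug. For iron and heme they covered iron uptake, storage and export, heme synthesis and breakdown, iron-sulfur cluster assembly, and chromatin dioxygenases that use iron. For metabolism they covered glycolysis, HIF targets, the pentose phosphate pathway, the TCA cycle, oxidative phosphorylation, cholesterol synthesis, fatty acid and lipid storage, and sphingolipids. For stress and signalling they covered the ATF4 amino acid response, the unfolded protein response, NRF2 targets, p53 targets, immediate early genes, the interferon response, apoptosis regulators, end joining and repair, autophagy and lysosome, the aryl hydrocarbon receptor, and JAK-STAT targets. For growth they covered DNA replication, mitosis, cell cycle inhibitors, and MYC and ribosome biogenesis. For cell types they covered stem cell, progenitor, megakaryocyte, erythroid, neutrophil and monocyte, B cell, T and NK cell, mast cell, basophil and eosinophil, and stromal and endothelial genes. Of 1111 list entries, 1009 matched a measured gene, 12 of them through a synonym. Each list with at least 5 measured members was tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Mouse Reactome pathways shipped with fgsea 1.28.0, of 15 to 200 measured genes, were tested with camera in the same way.

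The rule for named genes was also fixed beforehand. It took the 10 genes with the largest change in each direction among those that passed with groups that did not overlap. If fewer than 10 passed in a direction, it took the 10 with the smallest p in that direction instead, stated as not passing, without predicted genes and Rik clones. It added up to 3 passing members per list, and always Tfrc, Fth1 and Ftl1, with 1 further gene that is not reported here.

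The titles number the arrays 1 to 4 in both groups, which leaves open whether a number marks a shared set of animals. The deviations of each array from its group mean were therefore correlated across probe sets, before any calls were compared. For arrays of the same number the correlation was 0.241, 0.294, 0.192 and 0.142 for numbers 1 to 4, all over 0.1. For arrays of different numbers it ran from -0.208 to 0.171, and 3 of the 4 vehicle arrays correlated best with the eltrombopag array of their own number. Vehicle array 4 correlated at 0.171 with eltrombopag array 3 and at 0.142 with eltrombopag array 4. Across genes, the vehicle and eltrombopag differences between numbers 1 and 2 correlated at 0.175, and those between numbers 3 and 4 at -0.0083, so across genes the pairing of numbers 3 and 4 rests on their lying together. As every same-number correlation was over 0.1, the numbers were taken to pair the arrays, from these data and not from a statement in the labels. The fit with the number as a replicate block was 1 of the alternatives.

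The other alternatives fixed beforehand were a filter to genes with a mean above the median, quantile normalization once more, equal array medians, the mean of all probe sets of a gene, all probe sets without gene names, eBayes with trend and robust, array weights, a minimum fold of 1.5, an estimated correlation or fry for the lists, and each array left out in turn. Several more, listed in the closing section, were chosen after seeing the data.

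The gene and list tests were tested on simulated arrays for eltrombopag against vehicle, with 200 changed genes in each of 10 simulations. These were drawn with normal noise from the means and limma's moderated SDs of the 19505 genes. They hold no differences between replicate numbers, so the rates apply to such arrays and may differ for the real ones. limma recovered 40% of genes changed 1.5-fold, 96.2% of those changed 2-fold and 99.6% of those changed 3-fold. With no changed gene it made 0.2 false calls per simulation, and with genes changed 1.5-fold, 2-fold and 3-fold it made 5.5, 11.4 and 10. A log2 shift of 0.05 in all 71 genes of the oxidative phosphorylation list was called by camera in 20% of simulations and a shift of 0.1 in 100%, with genes drawn independently of each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.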

Results

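Transcripts were measured in hematopoietic stem cells of mouse bone marrow, sorted as lineage-negative cells with Sca-1, c-Kit and CD150 but without CD48 on their surface. The cells were cultured with stem cell factor and exposed for 16 h to eltrombopag at 10 µg/ml or to water as the vehicle. Eltrombopag is an oral drug that raises platelet and blood cell counts. It also binds iron. The comparison asks which transcripts of mouse stem cells differ after exposure to the drug. Each group held 4 arrays, numbered 1 to 4. The labels call them biological replicates without saying whether each came from its own animals, so p-values measure the spread between these samples.

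The 8 arrays were closely alike, and no array-level measure separated the 2 groups. Pearson correlations across genes lay between 0.9868 and 0.9933 for all pairs of arrays. The median log2 value was 6.68 ± 0.018 (SD, n = 4) with vehicle and 6.68 ± 0.014 (SD, n = 4) with eltrombopag. Its exact permutation p was 0.657, and the smallest exact permutation p among 7 array-level measures was 0.514 (adjusted p 0.943 for each). RMA had set the arrays to a common distribution, so the median and the quartiles could show little difference between the groups. The first principal component held 25.5% of the variance. It set arrays 1 and 2 of both groups (scores -18.8 to -11.0) apart from arrays 3 and 4 of both groups (scores 14.0 to 15.6). Transcripts of the Y-linked genes Uty and Kdm5d were high in array 3 of each group and low in the other 6 arrays. Eif2s3y, also Y-linked, had 4.73 in vehicle array 3, against 3.63 to 3.96 in the other vehicle arrays, but 3.996 in eltrombopag array 3, against 3.57 to 3.95 in the other eltrombopag arrays.

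**Figure D1:**
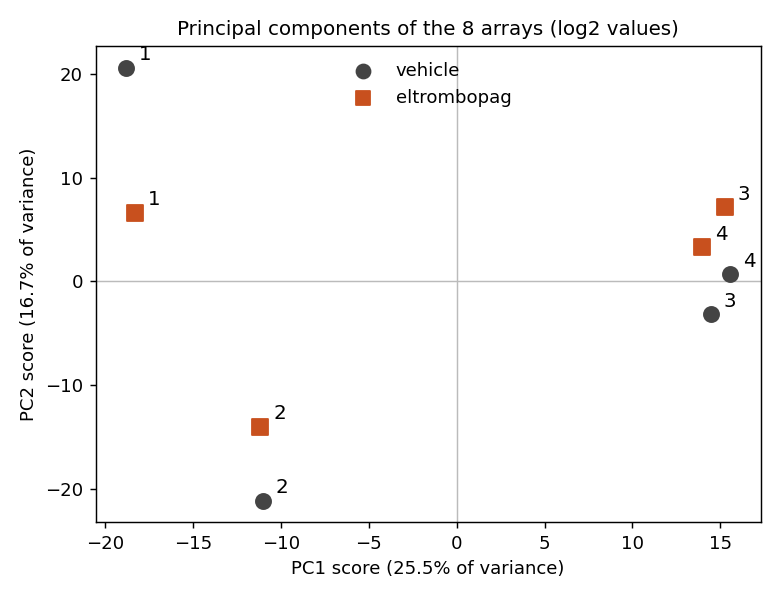
Scores of the 8 arrays on the first (horizontal) and second (vertical) principal components of the log2 values, with the replicate number beside each point. Arrays 1 and 2 of both groups lie left of 0 and arrays 3 and 4 of both groups lie right of 0, while vehicle and eltrombopag arrays are mixed.

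No gene passed the test between eltrombopag and vehicle. limma called 0 of 19505 genes, with a smallest adjusted p of 0.99978. At an unadjusted p under 0.05 there were 650 genes, 339 higher and 311 lower with eltrombopag, where chance alone would give 975. The 4 eltrombopag values lay entirely above the vehicle values for 218 genes and entirely below for 195, together 2.12% of genes against the 2.86% that chance gives. In 12.6% of genes the difference had the same direction in all 4 pairs, against 12.5% by chance. The median absolute log2 difference was 0.083, and 1 gene differed by over 1. The 95% interval of the difference excluded a 2-fold change in either direction for 19258 genes, which is 98.7% of them, and a 1.5-fold change for 88.0%. These intervals bound the array values and are not adjusted over genes. They cover dim genes too, and how far the array values of dim genes follow their transcripts is not known here.

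The genes named here had the smallest p-values in each direction and did not pass; each had an adjusted p of 0.99978 in limma. On the lower side stood Eomes, a T-box transcription factor, with a log2 value of 5.25 ± 0.093 (SD, n = 4) with vehicle and 4.65 ± 0.11 (SD, n = 4) with eltrombopag. Its log2 difference was -0.60 (SE 0.097), with the smallest unadjusted p of all genes, 8.89e-05. Rad51ap1, a DNA repair gene, differed by -0.62 (SE 0.11). Btg2, an antiproliferative gene induced by p53, differed by -0.58 (SE 0.11), and Aldoc, a glycolytic aldolase, by -0.57 (SE 0.13). Atp7a, a copper exporter, differed by -0.55 (SE 0.12). The remaining 5 were Fyttd1 (-0.51), an mRNA export adaptor, Cpne3 (-0.46), Gpr135 (-0.45), Dpep3 (-0.40) and Art1 (-0.39). On the higher side the log2 difference was 0.79 (SE 0.18) for Ano10, 0.76 (SE 0.19) for the glutathione transferase Gstm7 and 0.60 (SE 0.13) for Tmem184c. It was 0.54 for the tRNA methyltransferase gene Trmt12, 0.51 for the basement membrane collagen Col4a3, 0.49 for Zfp354a, 0.47 for the transcription factor Grhl3 and 0.41 for Gulp1, an adaptor in the uptake of dying cells. Vmn2r17 (0.39) and Olfr1173 (0.36) are chemosensory receptor genes whose log2 values lay near the dim end of the arrays, at 3.08 and 3.24 with vehicle. Dpep3 was dim too, at 3.97 with vehicle and 3.57 with eltrombopag. With eltrombopag, Eomes (4.65), Rad51ap1 (4.69) and Gpr135 (4.87) also lay below the arrays' mean lower quartile of 4.97. In all 20 genes the groups did not overlap, so the same direction in all 4 pairs is entailed and adds no support.

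**Figure D2:**
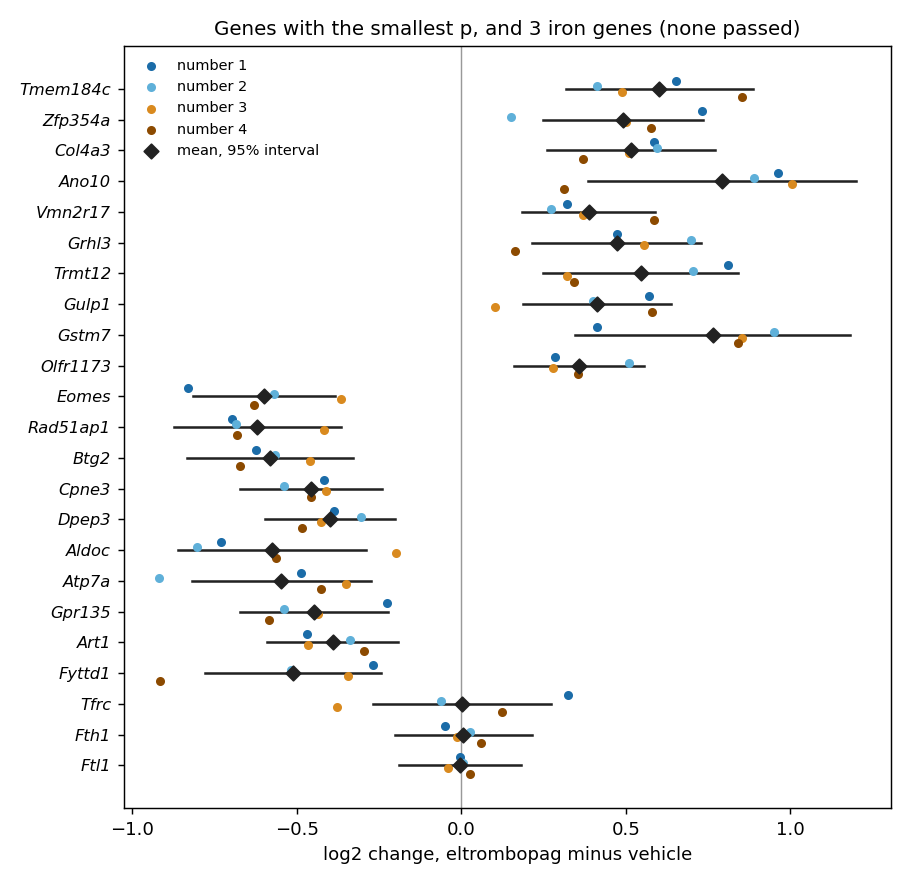
Log2 change with eltrombopag against vehicle (horizontal) for the 20 genes with the smallest p and for Tfrc, Fth1 and Ftl1; small points are the differences of the 4 same-numbered pairs, and diamonds with lines are means with 95% intervals from limma. The intervals of the 20 genes exclude 0, as their choice by p entails, while those of Tfrc, Fth1 and Ftl1 span it, and none of the 23 genes passed adjustment over all genes.

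None of the iron genes fixed in advance passed. Tfrc, the transferrin receptor that cells raise when iron is short, had a log2 value of 7.01 ± 0.16 (SD, n = 4) with vehicle and 7.01 ± 0.19 (SD, n = 4) with eltrombopag. Its log2 difference was 0.0024, with a 95% interval from -0.27 to 0.27. The transcripts of the ferritin chains that store iron differed by 0.0065 (interval -0.20 to 0.21) for Fth1 and -0.0028 (interval -0.19 to 0.18) for Ftl1. Ferritin protein was not measured here. Each of these 3 differences lay so near 0 that its sign changed with at least 1 other scaling of the arrays, and no direction is given. Of the 32 genes of iron uptake, storage and export, 18 were higher and 14 lower, with a median log2 difference of 0.020, and 0 passed, either over all genes or adjusted over the list alone. Among them, Slc11a2 and Slc40a1 were chosen after their values were seen. Slc11a2, an importer of ferrous iron, had 7.88 ± 0.18 (SD, n = 4) with vehicle and 8.26 ± 0.13 (SD, n = 4) with eltrombopag, a difference of 0.38 (SE 0.12, adjusted p 0.99978 in limma). Slc40a1, the iron exporter ferroportin, differed by -0.42 (SE 0.21, adjusted p 0.99978 in limma) and was lower in 4 of 4 pairs. With the replicate number as a block its SE was 0.088, and it did not pass either (adjusted p 0.984).

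The remaining iron and metabolic lists held 0 genes that passed over all genes. For heme synthesis and breakdown 8 of 17 genes were higher (median -0.022), for iron-sulfur cluster assembly 12 of 20 (0.014), and for iron-using chromatin dioxygenases 18 of 27 (0.040). Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, were higher in 62 of 71 cases, with a median log2 difference of 0.047. Among them Atp5k (0.27) and Ndufb9 (0.22) had the smallest p and were chosen after their values were seen. Without the replicate block, this was the only list with an unadjusted camera p under 0.05 (0.00633). It did not pass adjustment over the 36 lists (adjusted p 0.228), and its p was 0.459 with an estimated correlation. With the block, its unadjusted camera p was 0.0064. Erythroid markers (0.017) and glycolysis (0.037) were then under 0.05 too, and none of these lists passed adjustment. The oxidative phosphorylation list passed in some alternative settings, as with the filter on dim genes (adjusted p 0.0304), but not in others (range 0.0036 to 0.827 over 19 settings). It passed in none of the 19 with an estimated correlation. Glycolysis genes were higher in 10 of 22 cases (median -0.035, adjusted p 0.713). Besides Aldoc, Eno2 (-0.28) and Pgk1 (-0.17) were lower without passing, and were also chosen after their values were seen. HIF targets were higher in 17 of 37 cases (-0.0033), pentose phosphate genes in 5 of 9 (0.019) and TCA cycle genes in 10 of 23 (-0.0070). Cholesterol synthesis genes were higher in 9 of 19 (-0.0052), fatty acid and lipid storage genes in 16 of 34 (-0.0081) and sphingolipid genes in 7 of 19 (-0.032).

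No list of stress, signalling or growth genes passed, and 0 of their members passed over all genes. JAK-STAT targets, such as the feedback inhibitors of cytokine signalling, were higher in 12 of 26 cases, with a median log2 difference of -0.013. The ATF4 amino acid response was higher in 17 of 36 (median -0.028), the unfolded protein response in 10 of 27 (-0.037), NRF2 targets in 11 of 26 (-0.014) and p53 targets in 17 of 28 (0.025). Immediate early genes were higher in 11 of 29 (-0.015), interferon response genes in 20 of 33 (0.042), apoptosis regulators in 12 of 25 (-0.011) and genes of end joining and repair in 15 of 27 (0.022). Autophagy and lysosome genes were higher in 20 of 40 (0.0011) and aryl hydrocarbon receptor genes in 7 of 16 (-0.019). For growth, DNA replication genes were higher in 27 of 48 (0.021), mitosis genes in 20 of 49 (-0.031), cell cycle inhibitors in 10 of 18 (0.018), and MYC and ribosome biogenesis genes in 27 of 48 (0.022).

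No list of stem cell or lineage markers passed, and 0 of their members passed over all genes. Stem cell markers were higher in 14 of 36 cases (median -0.014), progenitor genes in 9 of 19 (-0.0053) and megakaryocyte markers in 8 of 21 (-0.022). Erythroid markers were higher in 14 of 19 (median 0.11, adjusted p 0.713). Their mean difference rested on number 3, with a mean change of 0.35 against 0.015 to 0.031 in the other 3 pairs. Among them the erythropoietin receptor Epor (0.34) and Icam4 (-0.23) had the smallest p, were chosen after their values were seen, and did not pass. Neutrophil and monocyte markers were higher in 13 of 28 (-0.017), B cell markers in 12 of 18 (0.056), and T and NK cell markers in 9 of 20 (-0.053). Mast cell, basophil and eosinophil markers were higher in 13 of 18 (0.028), and stromal and endothelial markers in 12 of 21 (0.087).

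Over the 36 lists, camera without the replicate block called 0, and 1 had an unadjusted p under 0.05. With an estimated correlation camera called 0 (0 unadjusted), and fry called 0 by direction (0 unadjusted) and 0 for change in either direction (1 unadjusted). Adjusted over the list alone, 3 genes passed in 6 lists, as 2 of them belong to several lists. This adjustment does not run across the 36 lists, so some passes can arise by chance. Over all genes, each of the 3 had an adjusted p of 0.99978 in limma. Aldoc passed in glycolysis (adjusted p 0.0242) and in HIF targets (adjusted p 0.0406). Btg2 passed in cell cycle inhibitors (adjusted p 0.00703), p53 targets (adjusted p 0.0109) and immediate early genes (adjusted p 0.0113). Tagln, an actin-binding protein of smooth muscle, passed in stromal and endothelial markers (adjusted p 0.0368), with a log2 difference of -0.55 (SE 0.13). The sign of the median, the mean and the test was not the same in 6 lists: cell cycle inhibitors, p53 targets, progenitor genes, megakaryocyte markers, fatty acid and lipid storage, and the ATF4 response.

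**Figure D3:**
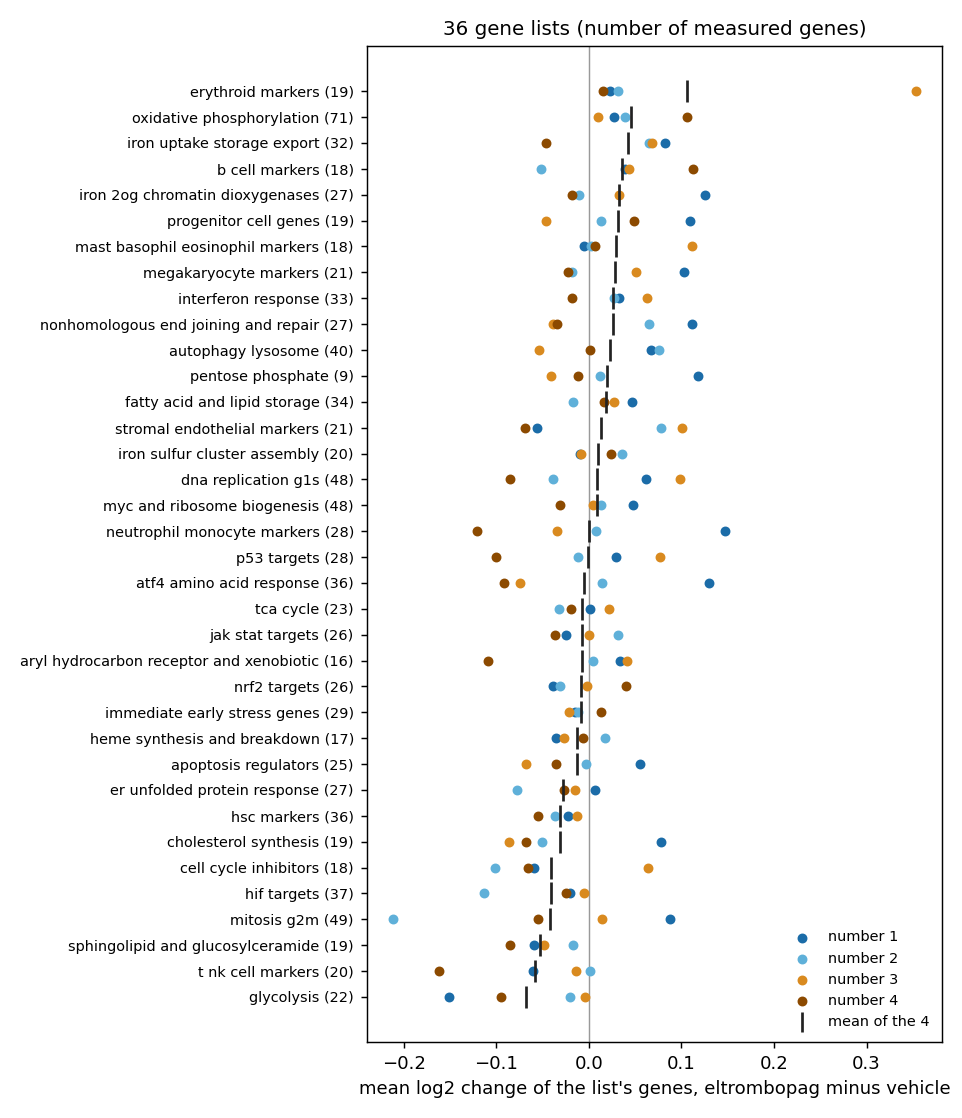
Mean log2 change with eltrombopag against vehicle (horizontal) over the measured genes of each of the 36 lists (vertical, with the number of genes); points are the 4 same-numbered pairs and bars are their means. The points of most lists fall on both sides of 0, those of oxidative phosphorylation lie between 0.010 and 0.11, and the erythroid mean is set by number 3 (0.35).

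Of 687 Reactome pathways, camera called 0, with 65 at an unadjusted p under 0.05. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05. The smallest adjusted p was 0.132, for mitochondrial translation initiation, elongation and termination, the making of proteins on mitochondrial ribosomes. In the initiation set 62 of 78 genes were higher, with a median log2 difference of 0.061 and a p of 0.144 with an estimated correlation. The Reactome glycolysis set had 15 of 24 genes lower, with a median of -0.065 and an adjusted p of 0.269. Packaging of telomere ends, a set made largely of histone genes, had 17 of 19 genes lower, with a median of -0.11 and the same adjusted p.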

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

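The tests in this part that weigh an explanation were chosen after the number pattern was seen. Single arrays that stood far from the other 3 of their group were looked for in 41 reported values, which makes 82 groups of 4. There were 6 such cases where chance gives about 4.1 (about 1 group in 20), and 4 of the 6 were the Y-linked genes Uty and Kdm5d, which were picked for their values.

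Uty had a log2 value of 7.71 in vehicle array 3, against 3.20 to 3.31 in the other vehicle arrays (gap over range 0.977), and 6.98 in eltrombopag array 3, against 3.02 to 3.23 (gap over range 0.947). Kdm5d had 7.08 in vehicle array 3, against 3.53 to 3.81 (0.923), and 6.36 in eltrombopag array 3, against 3.37 to 3.62 (0.915). Rad51ap1 had 5.53 in vehicle array 4, against 5.22 to 5.26 in the others (0.885). Eno2 had 5.44 in vehicle array 3, against 5.85 to 5.91 in the others (0.868).

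The Y-linked Uty and Kdm5d were thus high in both arrays numbered 3, and low in the arrays numbered 4, which lay with them on the first principal component. Eif2s3y, another Y-linked gene, was at 4.73 in vehicle array 3 but at 3.996 in eltrombopag array 3, near the 3.949 of eltrombopag array 1, and did not pass the test across the 4 numbers (adjusted p 0.465 in limma). Donor sex was tested as a cause of the difference between numbers 1 and 2 and numbers 3 and 4, described under the other observations. Numbers 1, 2 and 4 were alike low in Uty and Kdm5d, so sex would not part number 4 from numbers 1 and 2. Over all genes, the shift of number 3 from number 1 or 2 was correlated with the shift of number 4 from the other one, in arrays with none in common. The 4 correlations ran from 0.159 to 0.213 (median 0.184). With number 1 or 2 in the place of number 4, the highest was 0.038. Those values are no separate control: some are the values for number 4 with the sign turned. The others are 0.038, 0.015 and their negatives. Genes are also not independent replicates. Without the arrays numbered 3, limma called 49 genes for number 4 against numbers 1 and 2, and 0 with number 1 or number 2 set apart (1624, 1689 and 1096 at an unadjusted p under 0.05). These counts treat the 2 arrays of a number as independent, so they give no measure of the spread between numbers. The positive correlations argue against sex as the whole cause, though they rest on number 4 alone. A share of sex in the part carried by number 3 stays open.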

How the results depend on the processing

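The term for numbers 1 and 2 against 3 and 4, the fits on numbers 1 and 2 or on numbers 3 and 4 alone, the fit without both arrays numbered 3, and the random effect were chosen after seeing the data. The count of called genes was 0 in all 22 alternatives, among them every fit that left out 1 array. The replicate block left the calls of genes, lists and pathways at 0 and changed no other call; it gave 904 genes at an unadjusted p under 0.05 in place of 650, and the random effect gave 945. The filter to genes above the median gave 304, since it tests fewer genes. Within numbers 1 and 2 there were 650 and within numbers 3 and 4 there were 853. The genes named for the smallest p in each direction had groups that did not overlap. Leaving out arrays could therefore not turn their sign, and their kept signs are no support. Of 31 named genes, 28 kept their sign in every setting that held them, and the filter to genes above the median left some of them out. The 3 that did not, with differences near 0, were Tfrc (-0.00045 with quantile normalization, -0.0075 with equal medians, -0.021 with array weights and -0.13 in numbers 3 and 4 only), Ftl1 (0.0034 with quantile normalization, 0.0010 in numbers 1 and 2 only and 0.0095 without both arrays numbered 3) and Fth1 (-0.0034 with equal medians and -0.011 in numbers 1 and 2 only). The cause was not tested. Leaving out 1 array in turn moved Tfrc between -0.081 and 0.070, Fth1 between -0.041 and 0.037 and Ftl1 between -0.016 and 0.022. The lists called rose from 0 to 1 with the filter to genes above the median and with eBayes trend and robust (oxidative phosphorylation, higher, adjusted p 0.0304 and 0.0184, over a range of 0.0036 to 0.827). Leaving out 1 array gave 0 to 1: oxidative phosphorylation without vehicle 1 (adjusted p 0.00362), without eltrombopag 2 (0.0499) and without eltrombopag 3 (0.00613), and mitosis, lower, without eltrombopag 1 (0.0295; range 0.0295 to 0.994). These calls hold at the preset correlation only: with an estimated one, tried after seeing the data, both lists were called in 0 of the 19 settings (smallest adjusted p 0.832 for each). The Reactome calls rose from 0 to 3 with the filter, 3 with quantile normalization and 2 without both arrays numbered 3, and ran from 0 to 18 with 1 array left out (18 without eltrombopag 1, 9 without vehicle 3, 5 without eltrombopag 3). The cause was not tested. Oxidative phosphorylation was higher and glycolysis lower in all 19 settings. The arrays' signal over background was not used here, so how dim genes limit these counts is not known.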

Other observations

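The tests in this part were chosen after the results were seen. For the oxidative phosphorylation list, the predictions for the splits and for brightness were written before those tests were run. The list itself was picked from the data, as it had the smallest camera p of the 36 lists. Arrays 1 and 2 of both groups differed from arrays 3 and 4 of both groups. Of the 36 lists, the ATF4 response and megakaryocyte markers passed both at the preset and with an estimated correlation over the 8 arrays, but not with an estimated correlation over the means of the 4 numbers (adjusted p 0.868 for each). With treatment as a term, limma's test across the 4 replicate numbers called 41 genes. For 39 of them the largest of the 3 differences between pairs of numbers was 1 and 2 against 3 and 4. The 39 include genes set apart by 1 number, such as Boll, high in number 2 (mean 5.22, against 3.74 to 4.03 in the others). All 3 ways to part the numbers into pairs were then tested and adjusted together. Numbers 3 and 4 against 1 and 2 gave 89 called genes, 21 higher and 68 lower, and the other 2 ways gave 2 and 0. These calls and their SEs treat the 2 arrays of a number as independent. With the mean of each number as 1 value, 2 numbers against 2, limma called 44 genes, 41 of them among the 89, and the other 2 ways gave 0 and 0. The genes named in this and the next paragraph were chosen after their values were seen. Genes that ATF4 induces when amino acids are short were lower in numbers 3 and 4. Of 36 measured, 35 were lower, and 13 passed over the 8 arrays and 7 over the means of the numbers, with a median log2 difference of -0.69 (adjusted p 0.0225 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, fell by 2.54 (SE 0.12) and the glutathione-degrading Chac1 fell by 2.17 (SE 0.13). The log2 difference was -1.61 (SE 0.11) for asparagine synthetase Asns and -0.96 (SE 0.091) for the stress factor Ddit3, which did not pass over the means (adjusted p 0.0516). Of 26 JAK-STAT targets 18 were lower (median -0.14), and 4 passed over the 8 arrays and 3 over the means. The list lost its call with an estimated correlation (adjusted p 0.445). The log2 difference was -2.59 (SE 0.19) for Socs2, -1.89 (SE 0.11) for Cish and -1.08 (SE 0.097) for Pim1. Of 49 mitosis genes 43 were lower, and 6 passed over the 8 arrays, among them Cenpf (-0.97) and Plk1 (-0.88), but 0 over the means. The call of this list was lost too (adjusted p 0.245 with an estimated correlation).

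Other genes were higher in numbers 3 and 4. Alas2, the erythroid enzyme that starts heme synthesis, rose by 1.22 (SE 0.14). The log2 difference was 1.04 (SE 0.13) for the aldehyde dehydrogenase Aldh1a1 and 0.89 (SE 0.12) for the platelet protein Plek, which passed over the 8 arrays but not over the means (adjusted p 0.118 and 0.0740). Megakaryocyte markers were higher in 19 of 21 cases (median 0.29, adjusted p 0.0338 with an estimated correlation). Stem cell markers were higher in 28 of 36 (median 0.19) and DNA replication genes in 41 of 48 (median 0.20), and both lost their call with an estimated correlation (adjusted p 0.131 and 0.366). The only stem cell marker that passed over the 8 arrays, Ifitm1, went the other way, with a log2 difference of -1.33 (SE 0.095). It passed over the means too (adjusted p 0.0147 in limma). Of the 36 lists, camera called 8 at the preset correlation, adjusted over the 3 ways together, and 2 with an estimated one; over the means of the 4 numbers it called 9 and 0. The 2 called lists not yet given had an adjusted p with an estimated correlation of 0.422 for MYC and ribosome biogenesis and 0.588 for neutrophil and monocyte markers. List calls at the preset correlation were not confined to this way of parting the numbers. The other 2 ways gave 3 and 2 over the 8 arrays, and 3 and 3 over the means. With an estimated correlation they gave 0. The difference between eltrombopag and vehicle itself was not shown to depend on the numbers: the interaction called 0 genes in limma, with 738 at an unadjusted p under 0.05.

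For this difference between the numbers, scaling left by the normalization was tested, beside donor sex. After quantile normalization once more, 40 of the 41 genes were still called, so differences in distribution left between the deposited arrays do not carry these calls. RMA had already set the arrays to a common distribution. This step could therefore change little, and it cannot tell what the first normalization did. A batch of cell collection or culture that the labels do not name may be the source, and the labels name 2 models of cell sorter without saying which arrays each served. The shifts of the vehicle and the eltrombopag arrays between these numbers correlated across genes at 0.377, which such a batch and a difference between donor animals would both give, so these cannot be told apart. Apart from donor sex, which the shift of number 4 argues against as the whole cause, no biological explanation was tested, since the design names none for the numbers.

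The number of genes at an unadjusted p under 0.05, 650, lay below the 975 that chance gives. Of the 35 ways to split the 8 arrays into 4 and 4, 33 gave as many such genes, the real one among them. Chance cannot be excluded for this count, and the highest count of another split was 2144. That split set numbers 1 and 2 against 3 and 4 and called 198 genes, which points to a structure of the samples. In the 8 splits that part the 2 arrays of each number, the real one among them, the count ran from 630 to 757, while 17 of the other 27 gave over 975. This pattern is consistent with differences between replicate numbers widening the spread inside each group, and simulated arrays with no such differences and no changed gene gave a median of 956. With the replicate block the real split gave 904 and the other 7 gave 862 to 1024.

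For called genes, lists and Reactome pathways the real count between eltrombopag and vehicle was 0. Each of the 35 splits gives at least 0, so the splits decide nothing about these 3 counts. The highest other counts were 198 genes, 12 lists and 84 pathways. In the 8 splits that part all pairs, the highest counts of lists and pathways were both 0, and those above 0 came from splits that leave some pairs together.

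The lean of oxidative phosphorylation genes towards higher values with eltrombopag was small, with a median log2 difference of 0.047, and higher in 4 of 4 pairs by the list mean. In 8 of the 35 splits the list had a camera p as small as the real 0.00633 in either direction. Of these, 2 were among the 8 that part all pairs, and both counts include the real split. The smallest camera p of another split was 7.98e-08. Chance is therefore not excluded. The 8 splits that part all pairs are too few to have excluded it in any case. A trend of the change with brightness was tested against 10000 random lists matched on mean brightness. The real median lay at percentile 100 of them, above their highest value of 0.041, which argues against such a trend. Random lists do not share the correlation between members of this list, estimated at 0.275, so this percentile is no test of the drug, and an effect of eltrombopag stays open.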
